A study of Mus musculus with 21 samples.

How the data were processed

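Germinal centre B cells were profiled by mRNA sequencing in 16 libraries, and RNA crosslinked to the RNA-binding protein PTBP1 was mapped by iCLIP in 5 libraries, 21 samples in all. Germinal centres are the sites in lymphoid organs where activated B cells mutate their antibody genes and divide in a dark zone (DZ), and where they are selected in a light zone (LZ). iCLIP (individual-nucleotide crosslinking and immunoprecipitation) recovers, after UV crosslinking, the positions at which a protein touches RNA. Per the labels, control mice had loxP-flanked Ptbp1 alleles and wild-type Cd79a, and conditional knockout (cKO) mice had the same Ptbp1 alleles with a Cre recombinase gene in 1 Cd79a allele, which deletes in the B lineage. Per the series' design text, mice received NP-KLH in alum, and 7 days later splenic cells carrying IgD, CD3e, Gr1 or Ter119 were removed on a magnetic column before flow sorting. Each library came from a pool of 3 to 5 mice of 1 genotype and 1 sex. The 8 pools each gave 1 light zone and 1 dark zone library, and the pools of both genotypes with the same replicate number were sorted on 1 day. The 4 groups (LZ control, LZ cKO, DZ control, DZ cKO) therefore held 4 libraries each, with sort days 1 and 2 from males and sort days 3 and 4 from females.

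Per the labels' protocols, 2 ng of RNA per library was converted to cDNA from its poly(A) fraction with a low-input kit (SMART-Seq v4), and 0.5 ng of that cDNA was amplified over 8 PCR cycles. The deposited values of these libraries are raw counts, whole numbers per Ensembl gene identifier. Per the submitters' processing notes, Trim Galore 0.4.2, HISAT2 and HTSeq were used with the GRCm38 mouse genome. The versions of HISAT2 and HTSeq, the annotation release and the strand setting are not given in the sources used here. Overlapping and antisense genes, and near-identical copies such as histone genes and immunoglobulin segments, are therefore uncertain. Each file listed 47729 gene identifiers, of which 47224 were matched to a symbol, and 120 symbols were shared by several identifiers. The 5 summary lines that name no gene were kept out of library sizes and tests, and held 41.4% to 49.8% of all entries per library. Gene counts summed to between 26823882 and 34240096 per library. No pair of libraries of 1 group agreed within sampling noise, since the chi-square per degree of freedom was 22.2 to 167, so each library was counted as 1 replicate.

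Per the labels, the iCLIP libraries came from splenic B cells of female mice cultured for 48 h with lipopolysaccharide (LPS), a B cell mitogen. These are not germinal centre cells. The submitters' processing notes name Bowtie and GRCm38, and the barcodes held 4 random bases, which allow 256 distinct molecules per position. The deposited score of each site is a signed cDNA count, positive on the plus strand and negative on the minus strand, and is not scaled to depth. Per the file headers, sites were kept at a false discovery rate under 0.05 from 100 permutations within 15 nt, with regions treated separately, on mm10 with Ensembl 75. The deposited lists were 5 replicate lists and 1 list called by the authors after the cDNA counts of the replicates were summed. No control immunoprecipitation was used here.

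Genes were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr with a minimum count of 10, TMM scaling, robust quasi-likelihood fit, two-sided contrasts of group means). All 16 libraries entered 1 fit so that the groups shared an estimate of spread. A total of 15789 genes were tested, the common biological coefficient of variation was 40.3%, and calls are genes with a Benjamini-Hochberg (BH) adjusted p under 0.05. Levels are CPM, counts divided by library size and scaled by TMM, given as mean ± SD with n = 4, and changes are log2 fold changes ± SE. The 4 planned comparisons were cKO against control in each zone and light against dark zone in each genotype, with the interaction of zone and genotype as a further test. Gene lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, BH-adjusted over the lists tested. Camera was repeated with an estimated correlation, and with fry, which tests whether a list moves without comparing it with other genes. List means were compared by exact two-sided permutation of 4 against 4 unpaired libraries, for which the smallest possible p is 0.0286. Most lists must reach it for any to pass adjustment. The 28 lists of B cell programmes and 9 of other cell types held 815 symbols, 2 unmatched. The platelet and megakaryocyte list was not tested, as 2 members passed the filter, under the minimum of 3.

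The replicate number marks the sort day per the labels, and light and dark zone libraries of 1 number and genotype come from 1 pool, so the numbers pair the libraries. Deviations from the group means of libraries with the same number correlated at 0.0944 to 0.39. In each of the 6 pairs of groups, 4 of 4 libraries correlated best with the library of their own number. The block by sort day is an alternative fit, in which the coefficient of variation was 29.8%. Its value is given beside a result where it changes a call or moves a count by more than 1.5 times. The lists and comparisons, the fits, most alternatives and the rule for named genes were set before the data were examined. The rule names Ptbp1, Ptbp2, Ptbp3, Cd79a and Myc. In each comparison of genotypes or zones it adds the 8 largest rises and 8 largest falls among called genes with an average log2 CPM of at least 3 and the same sign on all 4 days. Gene segments of immunoglobulins and T cell receptors, pseudogenes and genes without a proper name are left out. It also takes up to 4 members of each list with the smallest adjusted p, the 3 smallest p of the interaction, the 6 genes with the most iCLIP sites, and named genes that hold a site. Some genes that the rule takes are not reported here.

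Sites were assigned to RefSeq gene spans on GRCm38.p6, the same build, where 1 span on any strand covered the position. The planned share of sites in 3′ UTRs, their pyrimidine content and 3′ UTR length strata were not run, because a genome sequence and exon annotation were not used here. The share of sites in the last 2 kb of protein-coding spans of at least 10 kb with at least 5 sites, read in the direction of the sites, and binding anywhere in the span took their place after the data had been seen. Called genes were compared with other protein-coding genes for holding a site by an exact two-sided test stratified into 10 bins of expression. No threshold for this test had been fixed. After an unadjusted p of 0.0448 was seen, the threshold was set on the p adjusted over the 4 tests.

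Alternatives covered the scaling (RLE, upper quartile), DESeq2 1.42.0, limma-voom, a minimum fold of 1.2, the low-count filter, sex as a covariate, each sex alone, fits of only the libraries compared, immunoglobulin and T cell receptor segments left out, and each library or day left out. Chosen after seeing the data were marker means of macrophages, plasma cells and T cells as covariates, the omission of 3 dark zone libraries with over 5% of counts in immunoglobulin genes, a block by pool, list tests that combine fry or the estimated correlation with the block, and the span-based iCLIP settings. The gene and list tests were run on 10 simulations from the light zone comparison of 15789 genes. Each changed 200 genes 1.5- to 4-fold, besides lists raised 1.2-fold. The tests recovered 30% of genes changed 1.5-fold, 65.7% at 2-fold and 90.9% at 4-fold. False calls made up 3.1% of calls on average and 0 to 6.34% per simulation, and 0 calls arose in the unchanged dark zone. Lists of 25 genes raised 1.2-fold were found in 97 of 100 cases with the preset correlation, 91 with the estimated one and 99 with fry. Each simulated gene was drawn independently, without effects of day or pool. These shares therefore do not carry over to real lists whose genes move together. Tables and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The p-values of single genes rest on the spread between libraries. Each pool gave 1 light zone and 1 dark zone library, and the main fit leaves the pool out. Camera and the tests of genes that hold a site or lie near Cd79a compare genes with other genes. The test of sites in the last 2 kb takes the 5 iCLIP replicates as its units.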

Results

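RNA was measured in germinal centre B cells sorted from the light and the dark zone of control mice and of mice that lost PTBP1 in the B lineage. PTBP1 (polypyrimidine tract binding protein 1) binds pyrimidine-rich RNA and regulates splicing, stability and translation. The series title asks whether it is needed for the selection of B cells in germinal centres. The 4 groups (LZ control, LZ cKO, DZ control, DZ cKO) held 4 libraries each, every one from a pool of 3 to 5 mice, and gene counts summed to between 26823882 and 34240096 per library. A further 5 iCLIP libraries mapped PTBP1 on RNA of cultured B cells.

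Ptbp1, the targeted gene, was low in every cKO library. Its level was 367, 353, 420 and 388 CPM in light zone control libraries 1 to 4 and 94.4, 96.2, 121 and 82.5 CPM in the matching cKO libraries. In the dark zone it was 416, 425, 448 and 486 CPM in control and 114, 100.1, 107 and 92.1 CPM in cKO libraries. Group means were 382 ± 28.9 (SD, n = 4) against 98.6 ± 16.4 CPM in the light zone, and 444 ± 31.4 against 103 ± 9.45 CPM in the dark zone. The cKO libraries thus kept 25.8% and 23.3% of the control level. Gene counts cannot tell transcripts that lack the deleted exons from intact ones, and the position of the deleted part is not given in the sources used here. The fall was 1.95 ± 0.11 log2 units below control in the light zone (edgeR log2 fold change = -1.95, adjusted p = 1.83e-07) and larger in the dark zone (-2.10 ± 0.11, adjusted p = 6.67e-08), without a difference between zones past the threshold (0.15, adjusted p = 1.0).

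The paralogue Ptbp2, which PTBP1 represses in other cells by making its mRNA subject to nonsense-mediated decay, was 13.2 ± 3.38 CPM in light zone control and 159 ± 29.7 CPM in light zone cKO cells (n = 4 each). The dark zone levels were 16 ± 2.31 and 216 ± 50.3 CPM in control and cKO cells. In edgeR, Ptbp2 rose by 3.60 ± 0.22 in the light zone (adjusted p = 2.05e-07) and by 3.75 ± 0.22 in the dark zone (adjusted p = 1.16e-07). The other paralogue, Ptbp3, did not pass the test in either zone. Its log2 fold change was 0.00012 ± 0.091 in the light zone (edgeR adjusted p = 1.0), with the opposite sign under upper-quartile scaling (-0.0098), and -0.18 ± 0.091 in the dark zone (edgeR adjusted p = 0.486). Cd79a, a signalling chain of the B cell receptor and the site of the Cre gene, was 2686 ± 283 against 1357 ± 245 CPM in the light zone and 2293 ± 233 against 949 ± 113 CPM in the dark zone. The cKO cells held 50.5% and 41.4% of the control level, with edgeR log2 fold changes of -0.98 ± 0.13 (adjusted p = 0.00151) and -1.27 ± 0.13 (adjusted p = 9.97e-05). Only the cKO mice carried the Cre allele, so its effects and those of the loss of PTBP1 cannot be separated in these groups. Myc, a growth regulator induced in selected cells, was at 132 ± 12.9 and 129 ± 27.1 CPM in light zone control and cKO cells and at 56.2 ± 5.81 and 68.4 ± 13.7 CPM in the dark zone. Its log2 fold changes with genotype were -0.03 ± 0.16 (edgeR adjusted p = 0.97) and 0.29 ± 0.16 (edgeR adjusted p = 0.539).

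**Figure D1:**
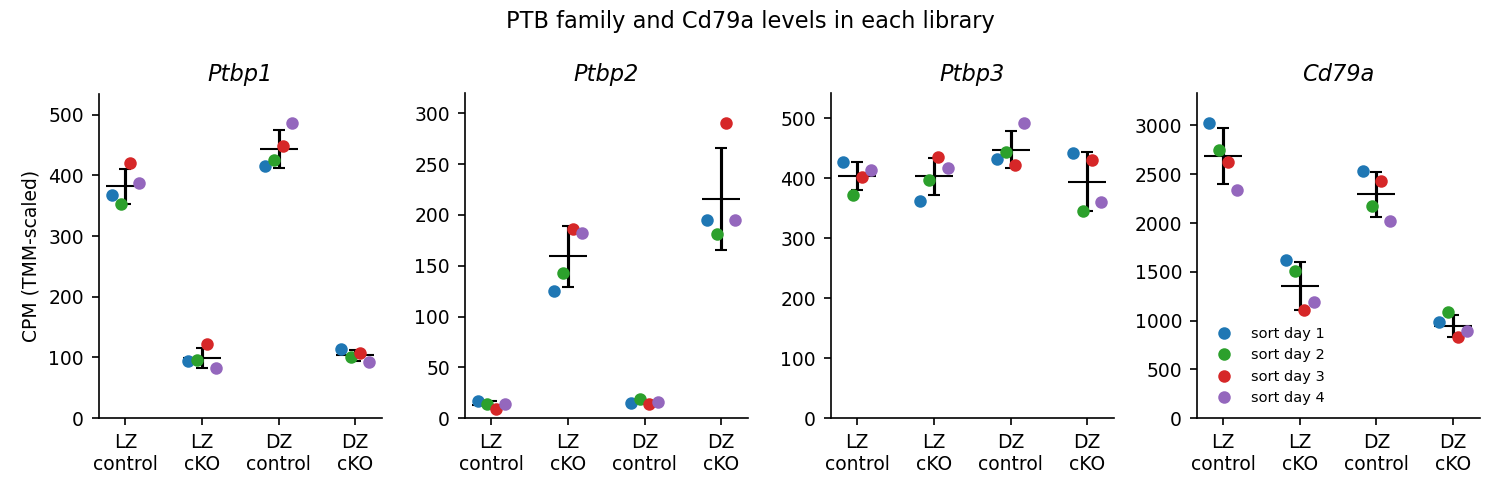
Levels of Ptbp1, Ptbp2, Ptbp3 and Cd79a (y axes, CPM scaled by TMM) in the 4 groups (x axis), with 1 point per library coloured by sort day, and bars for the mean ± SD. Ptbp1 was 82.5 to 121 CPM in all light zone cKO libraries and 353 to 420 CPM in light zone control libraries, and Ptbp2 was 126 to 290 CPM in cKO and 8.6 to 19.3 CPM in control libraries of both zones.

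The light zone comparison asks what changed in cKO mice in the cells that undergo selection. A rise of interferon-stimulated genes and of Ptbp2 stood beside lower levels of gene groups for cholesterol synthesis, DNA replication, MYC-regulated growth and RNA-binding hnRNP proteins. Single members of these groups mostly missed the threshold, and of the 18 lists that passed camera with a preset correlation between genes, 0 passed with an estimated one and 2 by fry. The light zone markers as a group did not pass the test. By edgeR, 171 of 15789 genes were called, 109 higher and 62 lower in cKO cells, of which 63 changed at least 2-fold and all 171 had the same sign on all 4 sort days.

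The genes named by size of change in each comparison had an average log2 CPM of at least 3. Besides Ptbp2, large rises in light zone cells by edgeR were those of Il9r, the interleukin-9 receptor (3.03 ± 0.41, adjusted p = 0.00204), and Ppfia4, a liprin scaffold protein (2.17 ± 0.21, adjusted p = 8.08e-05). Oas3, an interferon-induced sensor of double-stranded RNA, rose by 1.90 ± 0.38 (edgeR adjusted p = 0.0279), and Ass1, an enzyme of arginine synthesis, by 1.76 ± 0.18 (edgeR adjusted p = 8.21e-05). Carmil1, a regulator of actin capping, rose by 1.75 ± 0.36 (edgeR adjusted p = 0.0298), Ppl, the cytolinker periplakin, by 1.74 ± 0.30 (adjusted p = 0.0112), and Cmya5 by 1.68 ± 0.31 (adjusted p = 0.019). After Ptbp1, large falls by edgeR were those of Trio, a guanine nucleotide exchange factor (-1.09 ± 0.25, adjusted p = 0.0499), and Galnt12, which starts mucin-type O-glycans (-0.99 ± 0.14, adjusted p = 0.00286). Tmem106c (-0.98 ± 0.14, edgeR adjusted p = 0.00282), the myosin chaperone Unc45a (-0.97 ± 0.17, adjusted p = 0.0104) and Lrrc49 (-0.91 ± 0.21, adjusted p = 0.0475) fell as well. Over 37 alternatives, Lrrc49 missed the threshold in 28 and Trio in 22. The histone gene Hist1h2ao fell (-0.90 ± 0.19, edgeR adjusted p = 0.0319), but it shares sequence with other histone H2A copies, so its reads are uncertain.

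Among 28 interferon-stimulated genes, 4 rose and 0 fell in light zone cells, or 10 and 0 when adjusted over the list alone. The 4 were Xaf1 (1.14 ± 0.20, edgeR adjusted p = 0.0116), Oas3, the transcription factor Irf7 (0.65 ± 0.14, adjusted p = 0.0319) and the RNA sensor Ddx58 (1.05 ± 0.23, adjusted p = 0.0403), which missed the threshold in 19 of 37 alternatives. The list rose with a median of 0.576 (camera adjusted p = 1.04e-09, and adjusted p = 0.405 with an estimated correlation). The mean of the list was higher in cKO on each sort day, by 0.547 to 0.933. Of 9 genes that PTBP1 represses by splicing or nonsense-mediated decay in other cells, 1 rose (Ptbp2) and 0 fell, or 4 and 1 when adjusted over the list alone. This list rose with a median of 0.202 (camera adjusted p = 1.97e-05, and adjusted p = 0.209 with an estimated correlation), and Ptbp2 made up most of the change of its mean of 0.657. Its members Gabbr1 (0.89, edgeR adjusted p = 0.203, and 0.0341 with the sort-day block) and Mbnl1 (0.20, adjusted p = 0.198) were not called.

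Of 24 genes for cholesterol synthesis and uptake, 1 fell and 0 rose, or 10 and 0 when adjusted over the list alone. The called member was Hsd17b7 (-0.78 ± 0.17, edgeR adjusted p = 0.0399), while the sterol enzyme Lss (-0.75, adjusted p = 0.077, and 0.0155 with the sort-day block) missed the threshold. Hsd17b7 missed it in 20 of 37 alternatives. The list fell with a median of -0.323 (camera adjusted p = 7.39e-10, and adjusted p = 0.222 with an estimated correlation). Of 56 MYC-regulated growth genes, 1 fell and 0 rose, with or without adjustment over the list alone. This was Nop56 of the nucleolar box C/D complex (-0.32 ± 0.07, edgeR adjusted p = 0.0424), which missed the threshold in 23 of 37 alternatives, and the heat shock protein gene Hspe1 was at -0.37 (adjusted p = 0.104, and 0.0197 with the block). The list median was -0.181 (camera adjusted p = 1.64e-07, and adjusted p = 0.511 with an estimated correlation). Nop56 was also the 1 called member of the 37 ribosome biogenesis genes, whose median was -0.148 (camera adjusted p = 0.000103, and adjusted p = 0.697 with an estimated correlation).

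Genes of the cell cycle were lower as groups in light zone cKO cells, although 0 of their members were called by edgeR. The 32 DNA replication and G1/S genes had a median of -0.355 (camera adjusted p = 4.32e-11, and adjusted p = 0.511 with an estimated correlation). Pcna, the polymerase clamp, was at -0.47 (edgeR adjusted p = 0.191, and 0.00722 with the sort-day block), and 13 members of this list fell with the block. The 30 genes of G2 and mitosis had a median of -0.194 (camera adjusted p = 0.000103, and adjusted p = 0.697 with an estimated correlation). The dark zone genes, among them many mitotic genes, had a median of -0.174 (camera adjusted p = 0.00181, and adjusted p = 0.697 with an estimated correlation).

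RNA-binding hnRNP proteins (median -0.176, camera adjusted p = 0.000103, and adjusted p = 0.511 with an estimated correlation) and SR splicing factors (median -0.183, camera adjusted p = 0.00273, and adjusted p = 0.511 with an estimated correlation) were lower without a called member among 24 and 12 genes. The same held for genes of somatic hypermutation and class switching (median -0.188, camera adjusted p = 0.00595, and adjusted p = 0.651 with an estimated correlation) and of oxidative phosphorylation (median -0.0758, camera adjusted p = 0.00954, and adjusted p = 0.739 with an estimated correlation). It held also for the unfolded protein response (median -0.135, camera adjusted p = 0.0361, and adjusted p = 0.697 with an estimated correlation) and germinal centre B cell identity (median -0.0885, camera adjusted p = 0.0361, and adjusted p = 0.511 with an estimated correlation). Of 16 genes of naive and memory B cells, 1 rose, the oxysterol receptor gene Gpr183 (1.22 ± 0.21, edgeR adjusted p = 0.0105), or 4 with 1 lower when adjusted over the list alone. That list rose with a median of 0.631 (camera adjusted p = 0.0361, and adjusted p = 0.697 with an estimated correlation).

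The other programme lists did not pass camera in the light zone. Their adjusted p was 0.457 for the 33 light zone genes, of which Gpr183 rose, 0.366 for MHC class II presentation, 0.448 for ribosomal proteins, 0.457 for cell cycle inhibitors, 0.279 for p53 targets, 0.297 for neuronal genes and 0.726 for decay proteins that bind AU-rich elements. Apoptosis regulators (0.457) and immediate early genes (0.726) had positive medians and means but a negative test. Glycolysis (0.272), plasma cell genes (0.819) and the cytoskeleton (0.708) had negative medians and tests but positive means, and B cell receptor signalling (0.819) a positive median with a negative mean and test. The glucose transporter gene Slc2a3 rose (0.92 ± 0.19, edgeR adjusted p = 0.0295). The 3 genes of the PTB family, with 1 higher and 1 lower, had a positive median and mean and a negative test (adjusted p = 0.819).

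Markers of other cell types were measured beside these groups. In light zone cells, lists of neutrophils (median 2.44, camera adjusted p = 0.0361), NK cells (0.798, adjusted p = 0.0361) and dendritic cells (0.337, adjusted p = 0.0164) were higher in cKO libraries, each with adjusted p = 0.697 with an estimated correlation. Flt3, a receptor of dendritic cell progenitors, was the 1 called gene among them (1.14 ± 0.11, edgeR adjusted p = 8.08e-05). The macrophage list missed the threshold (median 0.639, camera adjusted p = 0.0792, and 0.00339 with the sort-day block), and the macrophage gene Lyz2 was at 79.2 ± 124 and 145 ± 125 CPM in control and cKO libraries. Lists of T cells (adjusted p = 0.457), erythroid cells (0.457) and stromal cells (0.819) did not pass camera. The platelet gene Itga2b rose by 5.45 ± 0.83 in the light zone (edgeR adjusted p = 0.00458).

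In the light zone, 18 of 36 lists passed camera with the preset correlation, 6 higher and 12 lower, 0 with an estimated correlation and 2 by fry. By exact two-sided permutation, 5 of 36 list means reached p = 0.0286, the smallest possible, so their BH-adjusted p of 0.206 cannot decide. These were the PTB family, genes that PTBP1 represses in other cells, p53 targets (difference 0.148), cholesterol genes and interferon-stimulated genes. In this permutation DNA replication (p = 0.171), MYC-regulated (p = 0.114), hnRNP (p = 0.0857) and G2 and mitosis genes (p = 0.4) did not reach it. The block by sort day raised the count of called genes from 171 to 868, 430 higher and 438 lower, and all 171 were among them. Within each sex, with 2 libraries per group, edgeR called 3 genes in males (Ptbp1, Ptbp2 and, chosen after its values were seen, Ikzf3, at 1.29 with adjusted p = 0.0127) and 9 in females. The count was 76, 89, 71 and 58 without light zone control library 1, 2, 3 and 4, and 102, 62 and 88 without light zone cKO library 1, 2 and 4, and fell to 50, 25, 62 and 17 without sort day 1, 2, 3 and 4.

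The dark zone comparison asks the same of the dividing cells. Ptbp2, Il9r and Ppfia4 rose there too, and genes of B cell receptor signalling, in large part Cd79a and Cr2, and of germinal centre identity were lower as groups. Interferon-stimulated genes were higher as a group, and so were markers of macrophages and of several other cell types. Of these lists, 0 passed with an estimated correlation and 0 by fry. MYC-regulated growth genes did not pass the test. By edgeR, 99 genes were called, 49 higher and 50 lower in cKO cells, of which 36 changed at least 2-fold, and all 99 had the same sign on all 4 days.

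Large rises in dark zone cells by edgeR after Ptbp2 were Il9r (2.36 ± 0.40, adjusted p = 0.0105), Ppfia4 (2.28 ± 0.22, adjusted p = 6.66e-05) and Abcb4, a phosphatidylcholine transporter (1.98 ± 0.15, adjusted p = 2.84e-06). Ppl rose by 1.70 ± 0.31 (edgeR adjusted p = 0.0169), Cfp, the complement regulator properdin, by 1.53 ± 0.20 (adjusted p = 0.00108), the membrane protein gene Stom by 1.45 ± 0.31 (adjusted p = 0.0484) and Ass1 by 1.43 ± 0.17 (adjusted p = 0.000712). After Ptbp1 and Cd79a, large falls by edgeR were those of Fah, an enzyme of tyrosine breakdown (-1.24 ± 0.25, adjusted p = 0.0364), and Isoc2b (-1.21 ± 0.22, adjusted p = 0.0194). Over 37 alternatives, Stom missed the threshold in 26 and Fah in 19. Galnt12 (-1.18 ± 0.14, edgeR adjusted p = 0.000641) and Unc45a (-1.14 ± 0.17, adjusted p = 0.00372) fell. Cr2, the complement receptor that lowers the threshold of B cell activation, fell by 1.15 ± 0.17 log2 units (edgeR log2 fold change = -1.15, adjusted p = 0.00409).

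Of 25 genes of B cell receptor signalling, 2 fell (Cd79a and Cr2) and 0 rose, or 3 and 0 when adjusted over the list alone. The list median was -0.0542 (camera adjusted p = 0.00296, and adjusted p = 0.458 with an estimated correlation). Cd79a, the site of the Cre gene, and Cr2 made up most of the change of the list mean (-0.142). Of 20 genes of germinal centre identity, 1 fell, the transcription factor gene Spib (-0.32 ± 0.065, edgeR adjusted p = 0.0345), which lies within 20 Mb of Cd79a and missed the threshold in 19 of 37 alternatives. The list had a median of -0.202 (camera adjusted p = 0.000516, and adjusted p = 0.366 with an estimated correlation). With the sort-day block, 4 members of this list fell. Of 28 interferon-stimulated genes, 1 rose, Oasl2 (1.29 ± 0.20, edgeR adjusted p = 0.00628), or 10 when adjusted over the list alone. Irf7 was at 0.61 (edgeR adjusted p = 0.0604, and 0.0172 with the sort-day block) and Oas3 at 1.51 (adjusted p = 0.0889, and 0.0161 with the block). The list rose with a median of 0.619 (camera adjusted p = 1.18e-09, and adjusted p = 0.458 with an estimated correlation). The list of genes that PTBP1 represses in other cells passed with a median of 0.0964 and 1 called member, Ptbp2, which made up most of the change of the list mean of 0.441 (camera adjusted p = 0.0123, 0.0932 with the sort-day block, and adjusted p = 0.458 with an estimated correlation). Another member, the actin crosslinker Flna, was at -0.62 (edgeR adjusted p = 0.316). The list was written from general knowledge, and no direction was fixed for single members.

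Several lists were lower in the dark zone by small amounts without a called member. These were hnRNP proteins (median -0.123, camera adjusted p = 0.00145, and adjusted p = 0.458 with an estimated correlation), SR proteins (-0.118, camera adjusted p = 0.0101, and adjusted p = 0.458 with an estimated correlation) and the cytoskeleton (-0.110, camera adjusted p = 0.0123, and adjusted p = 0.458 with an estimated correlation). In the last list 5 members fell when adjusted over the list alone, and Rac2, a GTPase of leukocyte migration, was at -0.31 (edgeR adjusted p = 0.0654, and 0.0127 with the sort-day block). DNA replication genes (median -0.162, camera adjusted p = 0.00211, and adjusted p = 0.651 with an estimated correlation), somatic hypermutation and class switching (-0.124, camera adjusted p = 0.00688, and adjusted p = 0.458 with an estimated correlation) and dark zone genes (-0.0931, camera adjusted p = 0.0262, and adjusted p = 0.615 with an estimated correlation) followed. Cholesterol genes had a median of -0.129 (camera adjusted p = 0.0456, and adjusted p = 0.603 with an estimated correlation), with Hsd17b7 at -0.66 (edgeR adjusted p = 0.096). The call of the cholesterol list was lost without sort day 1 (camera adjusted p = 0.282) or 4 (adjusted p = 0.292). With the macrophage marker mean as a covariate, cholesterol (camera adjusted p = 0.743) and DNA replication genes (adjusted p = 0.695) changed direction.

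Plasma cell genes were higher with a median of 0.600 (camera adjusted p = 0.0417, and adjusted p = 0.751 with an estimated correlation) and 0 of 16 called by edgeR. Without the 3 libraries rich in immunoglobulin RNA this list changed direction (camera adjusted p = 0.684), and without sort day 2 the call was lost (adjusted p = 0.601). Jchain, the joining chain of secreted antibody, was at 3397 and 5349 CPM in dark zone control and cKO libraries. Immunoglobulin genes took 6.87% of counts in dark zone control library 3, 8.94% in cKO library 2 and 9.44% in cKO library 3, against 2.04% to 3.26% in the other 13 libraries. Macrophage markers were higher with a median of 2.20 (camera adjusted p = 2.31e-06, and adjusted p = 0.458 with an estimated correlation), with 0 of 16 called by edgeR, 1 when adjusted over the list alone and 3 with the block. Lyz2 was at 82.5 ± 145 CPM in control and 383 ± 368 CPM in cKO libraries, and Cd68 at a log2 fold change of 1.40 (edgeR adjusted p = 0.0737, and 0.00298 with the sort-day block). Also higher were NK cells (median 1.31, camera adjusted p = 0.000153, and adjusted p = 0.458 with an estimated correlation), dendritic cells (1.18, adjusted p = 0.00443, and adjusted p = 0.458 with an estimated correlation) and erythroid cells (1.17, adjusted p = 0.00443, and adjusted p = 0.458 with an estimated correlation). T cells (0.744, camera adjusted p = 0.0123, and adjusted p = 0.651 with an estimated correlation) and neutrophils (1.36, camera adjusted p = 0.0441, and adjusted p = 0.603 with an estimated correlation) were higher as well. These markers were higher in the same comparison as the interferon-stimulated genes of the dark zone.

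The remaining lists did not pass camera in the dark zone. The adjusted p was 0.314 for MYC-regulated genes, 0.249 for ribosomal proteins, 0.279 for G2 and mitosis, 0.0975 for oxidative phosphorylation, 0.996 for MHC class II, 0.354 for the unfolded protein response, 0.0897 for neuronal genes and 0.307 for both cell cycle inhibitors and stromal cells. It was 0.271 for p53 targets, 0.223 for apoptosis regulators, 0.691 for immediate early genes, 0.826 for decay proteins and 0.208 for naive and memory B cells, which passed with the block (0.00434). The PTB family (0.271) also passed with the block (0.0272). Neither of these lists passed with the block and an estimated correlation together. Ribosome biogenesis (0.648) and light zone genes (0.932) had positive medians and negative tests, and glycolysis (0.485) a negative median and a positive mean.

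Among dark zone lists, 18 passed camera with the preset correlation, 9 higher and 9 lower, and 0 passed with an estimated correlation or by fry. With the macrophage marker mean as a covariate 8 passed, 5 of them among the 18. By exact two-sided permutation, 5 of 36 list means reached the smallest possible p of 0.0286 (BH-adjusted p = 0.206), and the macrophage mean differed by 2.69 at p = 0.0857. The 5 were the PTB family, genes that PTBP1 represses in other cells, germinal centre identity, p53 targets (difference 0.209) and interferon-stimulated genes. The sort-day block raised the count of called genes from 99 to 517, 300 higher and 217 lower, with all 99 among them. In males 2 genes (Ptbp1 and Ptbp2) and in females 4 genes (Ptbp1, Ptbp2, Cd79a and Abcb4) were called. The count was 62, 62, 49 and 62 without dark zone control library 3, control library 4, cKO library 2 and cKO library 4, 28, 34, 49 and 23 without sort day 1, 2, 3 and 4, and 29, with 25 shared, without the 3 libraries rich in immunoglobulin RNA.

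**Figure D2:**
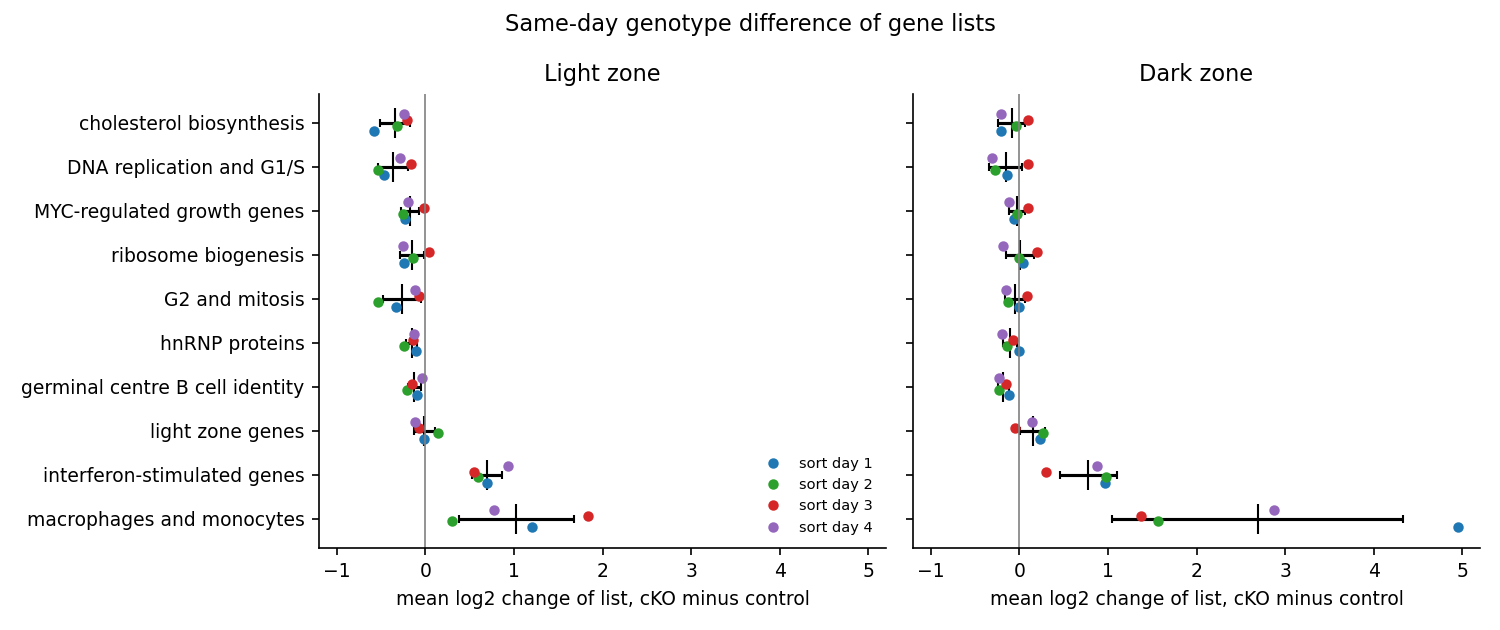
Same-day difference between cKO and control libraries (x axis, mean log2 change over the members of a list) for 10 gene lists (y axis) in the light zone (left) and dark zone (right), with 1 point per sort day, and bars for the mean ± SD over 4 days. Interferon-stimulated genes were higher on all 4 light zone days, by 0.547 to 0.933, and the macrophage markers of the dark zone had a mean of 2.69.

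A further question is whether the genotype effect differed between the zones. Of the 214 genes called in either zone, 207 had the same direction in both, 56 were called in both, 115 in the light zone alone and 43 in the dark zone alone. By direction, 28 genes were higher and 28 lower in both zones, against 0.338 and 0.196 for independent lists of these sizes. The 2 comparisons share no library, although light and dark zone libraries came from the same pools. Among the 214 genes, 0 had an interaction past the threshold. The interaction test called 0 of 15789 genes by edgeR, with 466 at an unadjusted p under 0.05, 0 by limma-voom, 6 by DESeq2 and 0 with the sort-day block. Without light zone control library 4, 1 gene was called, Dnajc27 (1.196, edgeR adjusted p = 0.0382). The 3 smallest p belonged to the antibody segment Igkv1-133 (-2.57 ± 0.40, edgeR adjusted p = 0.138), Dnajc27 (1.07 ± 0.18, adjusted p = 0.138) and the phosphatase gene Ptpn9 (0.91 ± 0.20, adjusted p = 1.0). Ptbp2 (-0.16), Ptbp3 (0.18), Cd79a (0.29) and Myc (-0.31) had an interaction adjusted p of 1.0 in edgeR. As lists, MYC-regulated growth genes (median -0.16, camera adjusted p = 2.07e-05) and cholesterol genes (median -0.277, camera adjusted p = 2.07e-05) were lower with genotype in the light zone than in the dark zone, both with adjusted p = 0.928 with an estimated correlation. In all, 12 lists passed camera here, 3 higher and 9 lower, and 0 with an estimated correlation or fry. With the sort-day block, T cells (camera adjusted p = 0.00998 against 0.115) and NK cells (0.00886 against 0.0908) passed and erythroid cells did not (0.0501 against 0.0427).

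The zone comparison in control mice asks which programmes separate the light from the dark zone in the presence of PTBP1. Light zone genes and MHC class II presentation were higher in light zone cells, by camera with a preset and with an estimated correlation. With the preset but not the estimated correlation, MYC-regulated and cholesterol genes were higher and genes of mitosis and oxidative phosphorylation lower (camera adjusted p = 0.377, 0.137, 0.364 and 0.463 with an estimated correlation). Cd83, a surface marker by which the zones are often told apart, was at 1500 CPM in the light and 371 CPM in the dark zone, and Cxcr4, the receptor that holds cells in the dark zone, at 38.4 and 82.1 CPM. Of 15789 genes, edgeR called 1183, 657 higher and 526 lower in the light zone, 370 of them by at least 2-fold and 1172 with the same sign on all days.

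Large rises in the light zone by edgeR, again among genes with an average log2 CPM of at least 3, were the chemokine receptor gene Ccr6 (3.68 ± 0.78, adjusted p = 0.00776), Cfp (2.72 ± 0.20, adjusted p = 1.6e-06) and Egr2, a transcription factor induced by antigen receptor signals (2.63 ± 0.45, adjusted p = 0.00172). The transcription factor genes Hhex (2.57 ± 0.42, edgeR adjusted p = 0.00113) and Bhlhe40 (2.57 ± 0.45, adjusted p = 0.00189) were of similar size. Lifr, a cytokine receptor gene, rose by 2.31 (edgeR adjusted p = 0.00174), the protease inhibitor gene Serpinb1a by 2.24 ± 0.38 (adjusted p = 0.00166) and the aldolase gene Aldoc by 2.23 ± 0.25 (adjusted p = 5.05e-05). Lower in the light zone by edgeR were Reln, which encodes reelin (-3.04 ± 0.54, adjusted p = 0.00231), the cell cycle regulator Rgcc (-2.46 ± 0.28, adjusted p = 5.69e-05) and the sodium channel gene Scn8a (-2.43 ± 0.27, adjusted p = 4.65e-05). Tifa, an adaptor of TRAF proteins (-2.32 ± 0.22, edgeR adjusted p = 1.31e-05), the recombination gene Mnd1 (-2.17, adjusted p = 0.000472) and the selenium carrier gene Selenop (-2.03 ± 0.15, adjusted p = 1.89e-06) were lower too. Lgr5, a receptor for R-spondins (-2.01, edgeR adjusted p = 2.32e-05), and Pafah1b3 (-1.99 ± 0.13, adjusted p = 2.86e-07) completed the 8 falls.

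Of 33 light zone genes, 24 rose and 0 fell (26 and 0 when adjusted over the list alone), with Cd83 (2.02 ± 0.096, edgeR adjusted p = 1.36e-08), the costimulatory ligand gene Cd86 (1.17 ± 0.092, adjusted p = 2.69e-06), Slamf1 (1.44 ± 0.12, adjusted p = 4.04e-06) and Relb of the NF-κB family (1.32 ± 0.14, adjusted p = 3.48e-05). The list passed camera (median 1.2, adjusted p = 7.76e-51, and adjusted p = 0.00612 with an estimated correlation). So did MHC class II presentation, with 9 of 10 genes higher, with or without adjustment over the list alone (median 0.704, adjusted p = 1.3e-19, and adjusted p = 0.0322 with an estimated correlation). Examples were H2-Aa (0.73 ± 0.079, edgeR adjusted p = 4.38e-05) and Ciita, the master regulator of the class (0.73 ± 0.095, adjusted p = 0.000199). Of 21 dark zone genes, 9 fell and 0 rose (14 and 0 when adjusted over the list alone), among them Cxcr4 (-1.10 ± 0.091, edgeR adjusted p = 4.39e-06) and Polh, the polymerase that writes A:T mutations (-1.19 ± 0.23, adjusted p = 0.00471). Their median was -0.752 (camera adjusted p = 1.97e-14, and adjusted p = 0.131 with an estimated correlation). Of 30 genes of G2 and mitosis, 10 fell (16 when adjusted over the list alone), such as Cenpf (-0.88 ± 0.19, edgeR adjusted p = 0.00883) and the kinetochore motor gene Cenpe (-0.73 ± 0.13, adjusted p = 0.00292), with a list median of -0.590 (camera adjusted p = 3.99e-14, and adjusted p = 0.364 with an estimated correlation).

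Growth genes went the other way. Of 56 MYC-regulated genes, 11 rose and 1 fell (20 and 2 when adjusted over the list alone), including Myc (1.23 ± 0.16, edgeR adjusted p = 0.000183) and the folate carrier gene Slc19a1 (1.48 ± 0.19, adjusted p = 0.000186), with a median of 0.230 (camera adjusted p = 2.03e-06, and adjusted p = 0.377 with an estimated correlation). Of 37 ribosome biogenesis genes, 7 rose (15 when adjusted over the list alone), with a median of 0.333 (camera adjusted p = 3.05e-07, and adjusted p = 0.444 with an estimated correlation). Nop56 (0.38 ± 0.07, edgeR adjusted p = 0.00278) and Pes1 (0.53 ± 0.078, adjusted p = 0.000547) were examples. Of 24 cholesterol genes, 10 rose (18 with 1 lower when adjusted over the list alone), with Dhcr7 at 0.82 ± 0.11 (edgeR adjusted p = 0.000289) and the regulator Srebf2 at 0.47 (adjusted p = 0.00182). Their median was 0.475 (camera adjusted p = 1.22e-09, and adjusted p = 0.137 with an estimated correlation).

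B cell receptor signalling had 8 of 25 genes higher and 1 lower (10 and 1 when adjusted over the list alone), among them Cr2 (1.56 ± 0.17, edgeR adjusted p = 5.05e-05), Ptpn6 (0.70 ± 0.073, adjusted p = 3.09e-05) and Cd22 (0.91 ± 0.11, adjusted p = 6.41e-05). Its median was 0.190 (camera adjusted p = 3.05e-07, and adjusted p = 0.176 with an estimated correlation). Naive and memory B cell genes (6 of 16 higher, 8 with 1 lower when adjusted over the list alone) included Fcer2a (1.78 ± 0.17, edgeR adjusted p = 1.4e-05) and Cd38 (1.45 ± 0.24, adjusted p = 0.00125), with a median of 1.11 (camera adjusted p = 1.54e-07, and adjusted p = 0.293 with an estimated correlation). The cytoskeleton list (2 of 24 higher, median 0.251, camera adjusted p = 0.000471, and adjusted p = 0.204 with an estimated correlation) included Rhof (0.79 ± 0.11, edgeR adjusted p = 0.00043). Genes that PTBP1 represses in other cells (1 of 9 higher, median 0.466, camera adjusted p = 0.0345, and adjusted p = 0.364 with an estimated correlation) included the phosphatase gene Ptprc (0.66 ± 0.088, edgeR adjusted p = 0.000242). T cell markers were higher in the light zone as well (median 1.42, camera adjusted p = 3.4e-05, and adjusted p = 0.514 with an estimated correlation).

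Oxidative phosphorylation (5 of 40 lower, 8 when adjusted over the list alone) had a median of -0.204 (camera adjusted p = 3.39e-08, and adjusted p = 0.463 with an estimated correlation), with Sdhb at -0.47 ± 0.088 (edgeR adjusted p = 0.00333). DNA replication genes (1 of 32 lower) had a median of -0.209 (camera adjusted p = 0.00423, and adjusted p = 0.723 with an estimated correlation). The hnRNP list was lower without a called member (median -0.106, camera adjusted p = 0.0345, and adjusted p = 0.590 with an estimated correlation). Apoptosis regulators missed the threshold (camera adjusted p = 0.0727, and 0.0412 with the sort-day block), though Bid (0.63 ± 0.083, edgeR adjusted p = 0.000218) and the survival genes Bcl2l1 (0.73 ± 0.14, adjusted p = 0.00445) and Bcl2 (1.95 ± 0.54, adjusted p = 0.0384) were among 4 that rose. Immediate early genes (camera adjusted p = 0.104, and 0.00249 with the block) included Egr1 (1.91 ± 0.37, edgeR adjusted p = 0.00465). Germinal centre identity genes split, with 3 higher and 4 lower (camera adjusted p = 0.303), and Gcsam (-1.75 ± 0.29, edgeR adjusted p = 0.00132) and Pou2af1 (-0.96 ± 0.14, adjusted p = 0.000582) were lower.

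Between the zones of control mice, 15 of 36 lists passed camera, 10 higher and 5 lower, 2 with an estimated correlation and 4 with that and the block. The exact permutation cannot decide, as its smallest possible p had a BH-adjusted p of 0.0936. The sort-day block raised the count of called genes from 1183 to 2166, males and females alone gave 288 and 257, and the T cell covariate gave 580. The count was 787 and 753 without light zone control library 1 and 2, and 603, 690, 631 and 576 without sort day 1, 2, 3 and 4.

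In cKO mice the same zone comparison called 1436 genes by edgeR, 776 higher and 660 lower in the light zone, 403 of them at least 2-fold. Between the genotypes, 461 of the higher and 348 of the lower genes were shared, against 32.3 and 22 for independent lists of these sizes. No library entered both comparisons, and the interaction, which tests their difference, called 0 genes by edgeR with 466 at an unadjusted p under 0.05. Ccr6 (4.12 ± 0.79, edgeR adjusted p = 0.00371), Egr2 (2.61 ± 0.46, adjusted p = 0.00189) and Hhex (2.55 ± 0.42, adjusted p = 0.00115) were higher. Serpinb1a (2.40 ± 0.38, edgeR adjusted p = 0.00095), Lifr (2.36 ± 0.39, adjusted p = 0.0013), Aldoc (2.34 ± 0.25, adjusted p = 3.22e-05) and Cfp (2.18 ± 0.20, adjusted p = 6.29e-06) followed, with Lrrc32, which presents latent TGF-β (2.16 ± 0.26, adjusted p = 9.24e-05). Large falls by edgeR were Reln (-2.76 ± 0.53, adjusted p = 0.00388), Lgr5 (-2.41 ± 0.21, adjusted p = 4.06e-06), Scn8a (-2.21 ± 0.26, adjusted p = 0.000101) and Mnd1 (-2.17 ± 0.31, adjusted p = 0.000479). Tifa (-2.01 ± 0.22, edgeR adjusted p = 3.73e-05), Selenop (-1.92 ± 0.15, adjusted p = 2.33e-06), the proline synthesis gene Pycr1 (-2.18 ± 0.63, adjusted p = 0.0411) and Jchain (-1.95 ± 0.47, adjusted p = 0.0164) were also lower. Without the 3 dark zone libraries rich in immunoglobulin RNA, Pycr1 was at -0.73 (edgeR adjusted p = 0.497) and Jchain at -0.69 (adjusted p = 0.151), and over 38 alternatives Pycr1 missed the threshold in 23. The sort-day block gave 2727 calls, and males and females alone 451 and 364. The count was 833 without light zone cKO library 2, 877, 716, 672 and 745 without sort day 1, 2, 3 and 4, and 672 without the 3 libraries rich in immunoglobulin RNA.

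**Figure D3:**
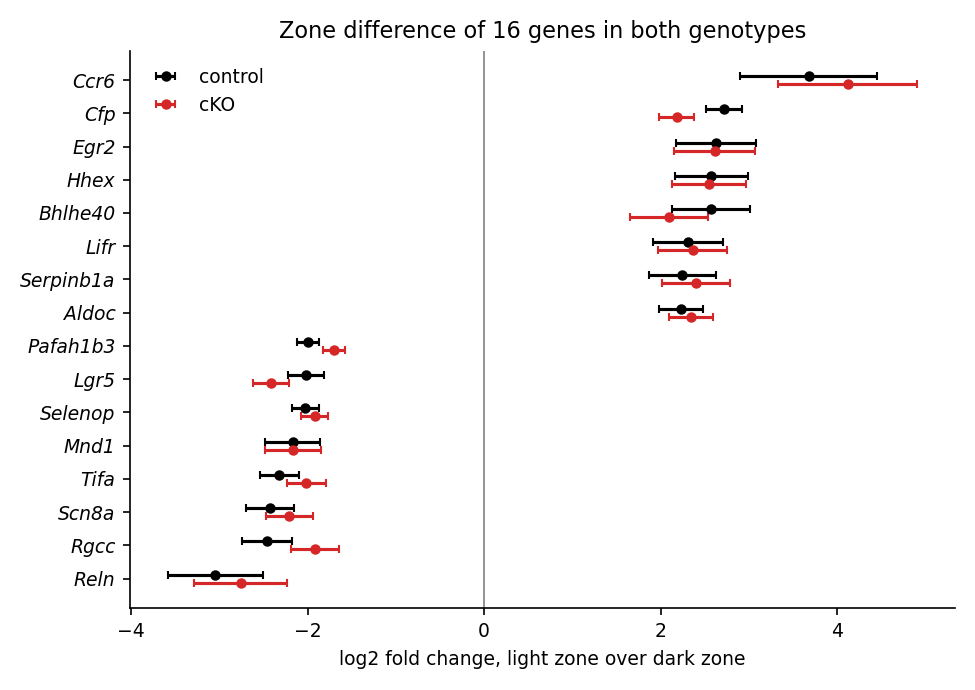
Log2 fold change of light over dark zone (x axis, ± SE) for the 8 largest rises and 8 largest falls in control mice (y axis) among called genes that have a proper name, an average log2 CPM of at least 3 and the same sign on all days, in control (black) and cKO mice (red). Ccr6 was at 3.68 in control and 4.12 in cKO mice, and Reln at -3.04 and -2.76.

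The iCLIP libraries ask where PTBP1 contacts RNA in B cells. Ebf1, a transcription factor of the B lineage, carried the most sites, 2632 (chromosome 11, 44618100 to 45008096, GRCm38), and the kinase gene Prkcb 1761 sites (chromosome 7, 122289104 to 122634402). Foxp1, Mbnl1, Bank1 and Arhgap15 followed with 1227, 1138, 1108 and 1088 sites. These counts were not scaled to gene length or expression. Ptbp2 held 138 sites with 220 cDNAs (chromosome 3, 119718741 to 119784647), Ptbp3 184 sites and Ptbp1 itself 11 sites that no other gene overlapped. Cd79a held 21 sites (chromosome 7, 24897497 to 24901858) and Myc 8. Of the named genes changed by genotype, Cr2 held 28 sites, Carmil1 17, Cfp 6, Il9r 5, Galnt12 and Trio 4 each, Ass1 and Cmya5 3 each, Ppl 2, and Stom and Unc45a 1 each, while Ppfia4, Abcb4, Oas3, Fah, Isoc2b, Tmem106c and Lrrc49 held 0. Of those that differed between zones, Ccr6 held 27 sites, Jchain 9, Bhlhe40 6, Pycr1 4, Reln 3, Lrrc32 2 and Lgr5 1, while Egr2, Hhex, Lifr, Serpinb1a, Aldoc, Rgcc, Scn8a, Tifa, Mnd1, Selenop and Pafah1b3 held 0. Dnajc27 of the interaction held 4 and Ptpn9 0. By cDNAs, a ribosomal RNA locus (Rn18s-rs5) had the most, with 19309.

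The pooled list held 244659 sites with 432167 cDNAs, and 72.6% of sites rested on 1 cDNA. The replicate lists held 17573, 28829, 6211, 45505 and 23100 sites. Of the pooled sites, 86.81% lay in 1 gene span, 7.59% lay outside all spans, and 7663 genes held at least 1. In genes with at least 5 sites, 98.13% of 4611 had all sites on 1 strand. Between replicate lists, 10.5% to 49.8% of sites had a neighbour within 15 nt on the same strand (median 34.4%), against a highest share of 3.16% after a shift of 1000 nt. Of the pooled sites, 19.9% lay near sites of at least 2 replicate lists and 10.08% near at least 3.

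In protein-coding spans of at least 10 kb, 5.9% of pooled sites fell in the last 2 kb of the transcribed direction, where even spacing gives 3.47%, and 2.48% in the first 2 kb. Over the 5 replicates the share was 5.01% ± 0.58 (SD, n = 5) against 3.47% ± 0.05 for even spacing, higher in 5 of 5 replicates. The difference of 1.54 ± 0.56 percentage points had an exact two-sided sign-flip p of 0.0625, the smallest that 5 replicates can give. In replicate 3, weighting sites by their cDNAs gave 4.55% in the last and 8.6% in the first 2 kb.

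Genes changed by genotype were then compared with others for holding a site in cultured B cells. Of 12274 protein-coding genes, 6078 (49.5%) held one. Among genes higher in light zone cKO cells, 45 of 97 (46.4%) did, an odds ratio of 0.638 (95% interval 0.402 to 1.01) within expression strata, with an exact two-sided p of 0.0448, or 0.179 adjusted over 4 tests. Among lower genes, 40 of 61 (65.6%) held a site, an odds ratio of 1.09 (0.59 to 2.05, exact p = 0.884). In the dark zone, 26 of 45 higher genes (odds ratio 0.946, 0.484 to 1.88, exact p = 0.874) and 35 of 49 lower genes (1.45, 0.728 to 3.04, exact p = 0.339) did. None of the 4 tests passed after adjustment. With called genes taken from the fit with the sort-day block, the odds ratio was 0.737 for light zone lower genes (adjusted p = 0.0169) and 0.614 for dark zone higher genes (adjusted p = 0.00104). Without strata, both tests of lower genes passed, with odds ratios of 1.95 (adjusted p = 0.0284) in the light zone and 2.56 (adjusted p = 0.00948) in the dark zone. With strata of span length they were 2.59 (adjusted p = 0.0048) and 2.6 (adjusted p = 0.00732), and with DESeq2 calls the value for dark zone higher genes was 0.679 (adjusted p = 0.0276).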

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

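The splits of the samples and all tests of explanations in this part were chosen after the results were seen.

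In the dark zone, the 16 macrophage markers were higher in cKO than control libraries on average (list mean difference 2.69, exact two-sided permutation p = 0.0857), with Lyz2 between 12.4 and 879 CPM in the 4 cKO libraries. A lower share of germinal centre B cells would raise every other cell type alike. The macrophage list exceeded the T cell list by 1.86 ± 0.626 (SE over 4 days). This cannot decide the question, because cells carrying CD3e had been removed before the sort. Neutrophil (2.27), NK cell (2.12), erythroid (1.37) and dendritic cell lists (1.15) were higher too, so a lower share stays open. The scaling between libraries is argued against by the same difference of 1.86, because a factor per library moves all genes alike. RNA from macrophages in the sorted fractions stays open as a candidate explanation, since within groups the markers moved together over the 16 libraries (median pairwise Spearman rho 0.725). Macrophages would have to pass a sort for B cells after the removal of cells carrying IgD, CD3e, Gr1 or Ter119. A difference between genotypes in macrophages attached to B cells was not tested.

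The rise of interferon-stimulated genes in light zone cKO libraries may have a technical or a biological source. With the macrophage marker mean as a covariate, the list mean difference was 0.584 ± 0.208 (SE), and 0.692 ± 0.237 without it. This argues against macrophage RNA as the whole source, but RNA of other cells was not tested. In the dark zone the values were 0.495 ± 0.236 and 0.779 ± 0.237, so macrophage RNA stays open there. A difference between sort days or sexes is argued against, as the lowest of the 4 same-day differences was 0.547. An effect of PTBP1 loss or of the Cre allele on the interferon response stays open as a hypothesis, and these groups cannot separate them.

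MYC-regulated growth genes and cholesterol genes (camera adjusted p = 2.07e-05 for both) stood out because their genotype effect was lower in the light than in the dark zone. More dark zone cells in the light zone gate of cKO mice stays open. Dark zone genes were lower there (mean -0.227 ± 0.0774, SE over 4 days, exact permutation p = 0.343), but many are mitotic genes, which were lower too. The zone difference was -0.149 ± 0.105 (SE) for MYC-regulated genes and -0.25 ± 0.115 for cholesterol genes. With the macrophage covariate it was -0.198 ± 0.0963 and -0.33 ± 0.0795, which argues against macrophage RNA in cKO dark zone libraries. A smaller induction of growth genes in the light zone of cKO mice stays open as a hypothesis, and neither list passed with an estimated correlation (adjusted p = 0.928 for both).

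The genotype effect differed between zones for 10 further lists by camera with the preset correlation, each with adjusted p = 0.928 with an estimated correlation. Lower in the light zone were ribosome biogenesis (adjusted p = 0.000441), DNA replication (0.000446), G2 and mitosis (0.00403), the unfolded protein response (0.00121), plasma cell genes (0.0187), macrophages (0.00121) and erythroid cells (0.0427). Higher were ribosomal proteins (0.0267), B cell receptor signalling (0.00362) and the cytoskeleton (0.0427). Ribosomal proteins changed direction without sort day 1 (camera adjusted p = 0.0506), and without the 3 libraries rich in immunoglobulin RNA 5 of all 12 lists passed, each lower in the light zone.

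Single libraries stood apart from the other 3 of their group in 9 measures, and 1 iCLIP replicate from the other 4. With 10 such cases among 187 groups of values, their share was close to the 5% that chance gives. The list mean (log2 CPM) of p53 target genes was 4.408 in light zone control library 1 (nearest other 4.467) and 4.755 in dark zone cKO library 2 (nearest other 4.504). For MYC-regulated genes it was 6.088 in light zone cKO library 3 (nearest other 5.788) and 5.953 in dark zone cKO library 3 (nearest other 5.735). For oxidative phosphorylation it was 6.993 in light zone cKO library 2 (nearest other 7.192), for cholesterol genes 5.476 in dark zone cKO library 3 (nearest other 5.208), and for neutrophil markers 2.149 in dark zone control library 2 (nearest other -2.328). Ptbp2 reached 290.4 CPM in dark zone cKO library 3, with 195.4 CPM as the nearest other. Immunoglobulin genes took 6.867% of counts in dark zone control library 3 and 3.157% in the nearest other. In iCLIP replicate 3, 28.77% of sites lay outside gene spans, against 15.5% in the nearest other replicate.

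Each comparison had 35 splits into 4 and 4, of its 8 libraries or, for the interaction, of the 8 pools of mice. For the 4 counts of called genes, no other split reached the real count. These splits take the libraries as unpaired although the sort day pairs them, so they cannot by themselves exclude chance. In the light zone the real split by genotype gave 171 genes and the highest other 52, which parted males from females. Within males and females the genotypes differed in 3 and 9 genes, and with the sort-day block in 868. The real and highest other counts in the dark zone were 99 and 16, between the zones of control mice 1183 and 1, and of cKO mice 1436 and 1, so in each of the 4 cases 1 split reached the real count. The interaction gave 0 genes by edgeR in the real split and at most 0 in the others, so 35 of 35 splits reached it, with 466 genes at an unadjusted p under 0.05 in the real split, 6 by DESeq2 and 0 by limma-voom. Among the 8 splits that part all 4 sort days, the highest other counts were 0, 1, 0 and 0 in these 4 comparisons of groups, but 8 splits are too few for a share under 0.05. For counts of lists that passed camera with the preset correlation chance cannot be excluded. In the light zone 5 of 35 splits reached the real 18 (highest other 21), in the dark zone 8 reached 18 (highest other 23), between the zones of control mice 16 reached 15 (highest other 26), and for the interaction 3 reached 12 (highest other 13). Among the 8 splits that part all 4 sort days, the highest other list counts in these comparisons were 14, 20, 20 and 7.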

How the results depend on the processing

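The marker covariates, the fit without the 3 dark zone libraries rich in immunoglobulin RNA, the block by pool, list tests that join fry or an estimated correlation with the block, span strata, protein-coding spans and the share of sites in the last 2 kb were chosen after seeing the data. The cause of a change was not tested unless given. The planned 3′ UTR share of sites, its windows, coding-sequence priority, pyrimidine content and length strata were not run. Fits within a sex have 2 libraries per group.

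Over the alternatives, 4730 of 5459 values of 145 named gene results kept direction and side of the threshold, 704 missed it, 4 newly passed it and 21 changed sign. Of 909 values of 63 list results, 610 kept both, 293 missed the threshold and 6 changed sign. For lists that had not passed, 92 of 1179 values had the opposite direction, 3 of them past the threshold, and 48 passed in the same direction.

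The replicate block by sort day gave 868, 517, 2166 and 2727 called genes, in place of 171, 99, 1183 and 1436 for the light zone, the dark zone and the zones of control and of cKO mice, and with this pairing 171, 99, 1179 and 1430 of the called genes were called again. It removed day-to-day spread, lowering the coefficient of variation from 40.3% to 29.8%. The block by animal pool gave 2186 and 2810 for the zones of control and cKO mice. Beyond these counts and the values given beside results, the block changed no call of a gene named as called. SR proteins between the zones of cKO mice passed camera with it (adjusted p = 0.0497, against 0.0982).

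DESeq2 called 587, 490, 1776 and 2214 genes in these comparisons and 6 for the interaction. The light zone count was 102 without a filter on low counts, where more genes were tested. With sex as a covariate the counts were 522 and 257 by genotype in the light and dark zone and 2266 between the zones of cKO mice. In fits of only the libraries compared they were 98, 52 and 820. Males alone gave 3 and 2 by genotype and 288 and 451 between zones in control and cKO mice, and females alone 9, 4, 257 and 364. A minimum fold of 1.2 gave 43, 36, 537 and 632, by construction fewer. Without the 3 dark zone libraries rich in immunoglobulin RNA, 29 genes were called by genotype in the dark zone and 672 between the zones of cKO mice. The T cell covariate gave 580 between the zones of control mice, and the macrophage covariate 1 gene for the interaction, Dennd3 (0.71, edgeR adjusted p = 0.0197), named after its values were seen.

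With a library or day left out, counts ranged from 17 to 195 in the light zone, 23 to 101 in the dark zone, 576 to 1213 and 672 to 1459 between the zones of control and cKO mice, and 0 to 1 for the interaction (1 without light zone control library 4, with 466 genes at an unadjusted p under 0.05 in the full edgeR fit). The lowest counts came without a sort day: 17, 23 and 576 without day 4 and 672 without day 3. With a day left out, 15 to 17 lists passed in the light zone, 14 to 17 in the dark zone, 15 to 17 between zones of control mice and 9 to 10 for the interaction.

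Of the lists past camera's threshold, 0 of 18 in the light zone, 0 of 18 in the dark zone, 2 of 15 between zones and 0 of 12 for the interaction passed with an estimated correlation, and 0, 0, 4 and 0 with that and the block. Fry gave 2, 0 and 0 for the light zone, dark zone and interaction, and with the block 8, 5 and 0. With the macrophage covariate 8 lists passed in the dark zone, where DNA replication (camera adjusted p = 0.695) and cholesterol genes (0.743) changed direction, as did macrophages for the interaction (0.877). Plasma cell genes in the dark zone changed direction with their own mean as covariate (camera adjusted p = 0.249) and without the 3 libraries rich in immunoglobulin RNA (0.684), where 5 lists passed for the interaction. Ribosomal proteins for the interaction changed direction without sort day 1 (camera adjusted p = 0.0506), the highest value with a day left out, and the lowest was 0.000614 without day 3.

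Signs changed for log2 fold changes near 0 that did not pass. Myc in the light zone was at 0.031 in females and ranged from -0.16 (without light zone cKO library 3) to 0.071 (without cKO library 4) with a library or day left out. Ptbp3 in the light zone was at -0.0098 with upper-quartile scaling, -0.00076 with limma-voom, -0.0022 without and -0.0038 with a stricter filter, -0.0014 with sex, -0.00090 with only the libraries compared, -0.066 in males and -0.0047 without immunoglobulin and T cell receptor segments. With a library or day left out Ptbp3 ranged from -0.045 (without day 3) to 0.067 (without day 1).

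Odds ratios of holding a site also changed. For light zone higher genes the value was 1.37 with sites near at least 3 replicate lists. For light zone lower genes it was 0.973 and 0.955 with sites near at least 2 and 3 lists, 0.535 with scores above the upper quartile, 0.737 with calls under the block, 1.95 without strata and 2.59 with strata of span length. For dark zone higher genes it was 1.78 with at least 3 lists, 1.04 with high scores, 1.4 without strata, 1.08 with span strata, 1.00 with protein-coding spans, 0.614 with calls under the block and 0.679 with DESeq2 calls. For dark zone lower genes it was 0.905 with high scores, 2.56 without strata, 2.6 with span strata and 0.903 with DESeq2 calls. After adjustment over 4 tests, 0 passed in the test as reported (1 at an unadjusted p under 0.05), and 2 passed with calls under the block, without strata and with span strata, and 1 with DESeq2 calls. The share of sites in the last 2 kb was 7.09% for sites near at least 3 replicate lists, and the mean over replicates was 4.82% to 5.15% with a replicate left out.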

Other observations

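The genes in this part that the naming rule does not take were chosen after their values were seen, and so were the tests on Cd79a copies and on Ptbp1 counts left in cKO libraries.

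Ikzf3, which encodes the transcription factor Aiolos, was at 397 ± 28.2 CPM in light zone control and 947 ± 48.8 CPM in cKO cells (SD, n = 4), and at 450 ± 35.2 and 920 ± 71.7 CPM in the dark zone. Its log2 fold changes were 1.25 ± 0.080 (edgeR adjusted p = 3.65e-07) and 1.03 ± 0.080 (adjusted p = 4.29e-06). Lmo2, a transcriptional cofactor of germinal centre cells, rose by 0.61 (edgeR adjusted p = 0.00605) in the light zone and 0.92 (adjusted p = 0.000146) in the dark zone. Fcgr2b, the inhibitory Fc receptor, rose by 0.29 (edgeR adjusted p = 0.0436) and 0.34 (adjusted p = 0.0241), and Cmah, an enzyme of sialic acid modification, by 0.73 (adjusted p = 0.00539) and 0.75 (adjusted p = 0.00407). Fscn1 (1.55, edgeR adjusted p = 0.00718, and 1.36, adjusted p = 0.0216), Gsn (0.71, adjusted p = 0.00718, and 0.67, adjusted p = 0.0125) and Pdlim7 (0.92, adjusted p = 0.00124, and 1.13, adjusted p = 0.000118) rose. Cd2ap (-0.66, edgeR adjusted p = 0.00786, and -0.89, adjusted p = 0.000724) fell, as did the adhesion gene Icam2 (-0.59, adjusted p = 0.00456, and -0.54, adjusted p = 0.00815) and the DNA sensor gene Aim2 (-0.75, adjusted p = 0.00659, and -0.68, adjusted p = 0.014).

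Immunoglobulin constant region genes differed in size but mostly missed the threshold. In the light zone Ighm was at -1.14 ± 0.36 (edgeR adjusted p = 0.16, and 0.0392 with the sort-day block) and Ighg3 at -1.97 ± 0.65 (adjusted p = 0.175, and 0.0471 with the block). In the dark zone Ighg1 was at 1.57 ± 0.54 (edgeR adjusted p = 0.226, and 0.0142 with the block) and Ighe at 3.60 ± 0.88 (adjusted p = 0.0857, and 0.000882 with the block). In cKO mice, plasma cell genes (3 of 16 lower in the light zone, median -1.02, camera adjusted p = 0.00116, and adjusted p = 0.704 with an estimated correlation) and genes of the unfolded protein response (4 of 20 lower, median -0.556, camera adjusted p = 0.00342, and adjusted p = 0.676 with an estimated correlation) separated the zones. Dark zone cKO libraries 2 and 3 held 8.94% and 9.44% of counts in immunoglobulin genes, with Jchain at 7535 and 9409 CPM, against 1975 and 2479 CPM in libraries 1 and 4. In control mice the camera adjusted p of these lists was 0.114 and 0.495.

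Genes called in either zone were more frequent near Cd79a on chromosome 7, in line with the hypothesis of flanking strain DNA carried with the Cre allele, with 12 of 351 genes within 20 Mb (3.42%) against 1.56% elsewhere (one-sided Fisher exact p = 0.0116), while 5.42% of other windows held a share as high. They included Akt2 (0.41 in the light zone, edgeR adjusted p = 0.0255, and 0.49 in the dark zone, adjusted p = 0.00917) and Blvrb (-0.51, adjusted p = 0.0104, and -0.42, adjusted p = 0.0396).

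Loss of 1 of 2 Cd79a copies predicts a log2 change of minus 1. The light zone value lay 0.117 SE from it. The dark zone value lay 2.09 SE from it, just past a limit of 2 SE set after the values were seen. The interaction of zone and genotype did not pass for Cd79a. The loss of 1 copy as the whole cause is therefore not decided for the dark zone. RNA from macrophages or T cells as the source of the Ptbp1 counts left in cKO libraries is argued against, since the highest of 8 cKO libraries was 1.47 times the lowest for Ptbp1, 70.9 times for Lyz2 and 11.3 times for Cd3e. For the hypothesis that transcripts bound by PTBP1 are released after its loss, 18 of 26 genes higher in both zones held a site (69.2% against 49.5%, odds ratio 1.15, 95% interval 0.455 to 3.18, exact two-sided p = 0.831), an interval too wide to decide.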
